A study of Mus musculus with 12 samples.

How the data were processed

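Gene expression was measured on 12 Illumina bead arrays of mouse alveolar type II cells, the lung cells that make surfactant. Per the labels, mice were left untreated or received Pseudomonas aeruginosa, a bacterium that infects and injures the lung, by the i.t. route. Type II cells were then isolated from the lungs, at 72 h in the treated mice, and sorted into cells with and without Sca-1, a surface protein that the gene Ly6a encodes and that several kinds of stem and progenitor cell carry. This gave 4 groups with 3 arrays each: Sca-1 neg untreated, Sca-1 pos untreated, Sca-1 neg treated and Sca-1 pos treated. The labels name no group that received a vehicle alone. Below, infection therefore stands for the bacterium and the i.t. procedure together, which this design cannot tell apart. Total RNA was extracted with Trizol, purified on a column and labelled with biotin.

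The authors deposited the scanner intensity of each probe on each array, on a linear scale, without background subtraction and without normalization between arrays; it ran from 71.5 to 49729.7. Per the file headers, each intensity stood beside a detection p-value, which was low where the probe was brighter than the negative control beads of its array and moved in steps of 1/936 on all arrays. A second deposited table held intensity values that the authors had quantile normalized between the arrays. Its sorted values differed from the mean of the sorted scanner columns by at most 0.0807%, its column medians were all 93.1, and it was neither log-transformed nor corrected for background. The scanner, the summary software and their versions were not given in the sources used here, nor were the slides or the dates.

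The tables held 45281 probes. A table that pairs probes with genes gave 1 symbol for 34885 of them, several for 18 and none for 10378. Symbols were brought up to date through gene identifiers or transcript accessions for 34818 probes, and 10 symbols changed. Scanner intensities were processed in R 4.3.3 with limma 3.58.1. The neqc function corrected for background with the detection p-values, added an offset of 16, quantile normalized the arrays and took log2. A probe was kept when its detection p was under 0.01 on at least 3 of the 12 arrays, which left 18100 probes, 15640 of them with 1 gene symbol. Each gene was represented by its probe with the highest mean over all arrays, so that 5437 further probes were not used and 10203 genes were tested.

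A mean per group was fitted to all 12 arrays at once, with 8 residual degrees of freedom, and limma's moderated test was applied to 4 comparisons of 2 groups and to the interaction of Sca-1 fraction and treatment. The interaction is the change from untreated to treated in Sca-1 pos cells minus that change in Sca-1 neg cells. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was said to rise, fall or change at an adjusted p under 0.05. Fold changes are given on the log2 scale with their standard error (SE), which is estimated from all 12 arrays. Where a gene was detected on none of the 3 arrays of a group by any of its probes, or the group's mean lay below the level a probe needs to be detected, the fitted fold depends on the offset. In that case the fold is given as a lower bound, with each array of that group at that level or at its own value if higher, and written as at least so many fold. The part of this rule on the group's mean, and the interaction medians at the detection level, were chosen after the values were seen.

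The design, the tests, 27 gene lists and the rule for naming genes were fixed before the data were examined. The lists covered cell types of the lung, stem and progenitor associated genes, and pathways of infection, division, lipid synthesis and injury; they held 737 distinct genes, of which 480 were measured. The list of stem and progenitor associated genes held 48 genes, was written from general knowledge and not taken from the study, and had 28 measured members, 9 of which another list also held. Lists were tested with camera in limma with a preset correlation of 0.01 between genes, and adjusted over the 27 lists within a comparison. The calls were repeated with the correlation estimated from the data, and with fry, which tests whether the genes of a list move, on balance, in the same direction. With an estimated correlation no list passed in any comparison, and this adjusted p is given beside each call. For each list, members were also counted with p-values adjusted over the list alone. Where a list had members detected on no array of a group, its median was also computed with them at their bounds, and for the interaction with every value below the detection level of its array set to that level.

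The rule named Ly6a first, then for each comparison of 2 groups the 10 genes with the largest rise and the 10 with the largest fall among those with an adjusted p under 0.05 whose groups of 3 arrays did not overlap, so that all 3 arrays of the higher group lay above all 3 of the lower. For the interaction it took 5 genes of each sign. For each list it took up to 4 members with the smallest adjusted p among those that changed, and up to 4 of the brightest members of cell type lists as levels. No probe carried the symbol Ly6a, so the gene that defines the sort could not be reported.

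Alternatives covered no background correction, median scaling, the deposited normalized values, another offset, other detection filters, every probe as a feature, another variance model, array weights, a minimum of 2-fold, only the 6 arrays compared, the replicate number as a block, and leaving out each array in turn. Slide as a block was not run, since slides were not given. A further 3 alternatives were chosen after the data were seen: leaving out Sca-1 neg untreated arrays 1 and 2, leaving out list members that another list holds, and a fit of 6 arrays with the replicate number as a block. The labels do not say whether replicates came from separate animals, so the p-values measure the spread between these samples, part of which may be technical. The number of arrays limits the precision.

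The procedure was tested on simulated data made with each gene's spread pooled over the real arrays, with 200 of 10203 genes changed. For Sca-1 pos against Sca-1 neg, untreated, 25.4% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 92.4% of those changed 4-fold were recovered, with 5 false calls. For the same comparison in treated mice the shares were 17.9%, 55.2% and 97.0%, with 5 false calls. They were 26.9%, 65.7% and 95.5%, with 9 false calls, for treated against untreated Sca-1 neg cells, and 17.9%, 68.7% and 93.9%, with 11 false calls, for Sca-1 pos cells. For the interaction, 0% at 1.5-fold, 20.9% at 2-fold and 81.8% at 4-fold were recovered, with 5 false calls. Of 20 simulated lists of 28 genes, that moved by 0.5 on the log2 scale was called in each comparison, and no other list was called by camera in any. Genes were simulated independently of one another, so false calls for lists whose members vary together were not tested. Every group had the same spread and no detection limit. Recovery and false calls were therefore not tested for a group that spreads more, as the Sca-1 neg untreated arrays did. Nor were they tested for genes below the detection level or for larger shares of changed genes.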

Results

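Expression was compared between Sca-1 pos and Sca-1 neg type II cells of untreated mice and of mice 72 h after P. aeruginosa, with 3 arrays in each of 4 groups. The mean number of probes detected per array was 16002.7 ± 150 (SD, n = 3) in Sca-1 neg untreated, 17322.7 ± 192 in Sca-1 pos untreated, 14906 ± 262 in Sca-1 neg treated and 16096.7 ± 404 in Sca-1 pos treated cells. The mean scanner intensity of an array lay between 286 and 498. Sftpc, which encodes surfactant protein C and marks type II cells, was bright in every group, with mean log2 levels of 14.39 in Sca-1 neg untreated, 14.17 in Sca-1 pos untreated, 14.69 in Sca-1 neg treated and 14.57 in Sca-1 pos treated cells. Ly6a itself could not be followed, since no probe carried its symbol.

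The first principal component held 58.8% of the variance and set Sca-1 pos arrays apart from Sca-1 neg arrays. The second held 18.0% and set treated arrays apart from untreated ones. Replicates correlated across genes at r from 0.958 (array 1 with array 3) to 0.984 in Sca-1 neg untreated cells and from 0.971 to 0.989 in the other groups; genes are not independent replicates. Actb, which encodes a cytoskeletal actin and was looked at after the values were seen, stood at 11.38 and 12.39 on Sca-1 neg untreated arrays 1 and 2 and at 13.84 on array 3. On the arrays of the other groups it stood between 13.82 and 14.18, so for this gene arrays 1 and 2 were the ones apart. Transcripts that tell the sexes apart were mixed: Xist, made from the inactive X chromosome, was detected without the Y-linked Eif2s3y on 4 arrays, Eif2s3y without Xist on 4, and both on 4. No Sca-1 pos untreated array held Xist without Eif2s3y, so sex was not balanced between the groups.

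**Figure D1:**
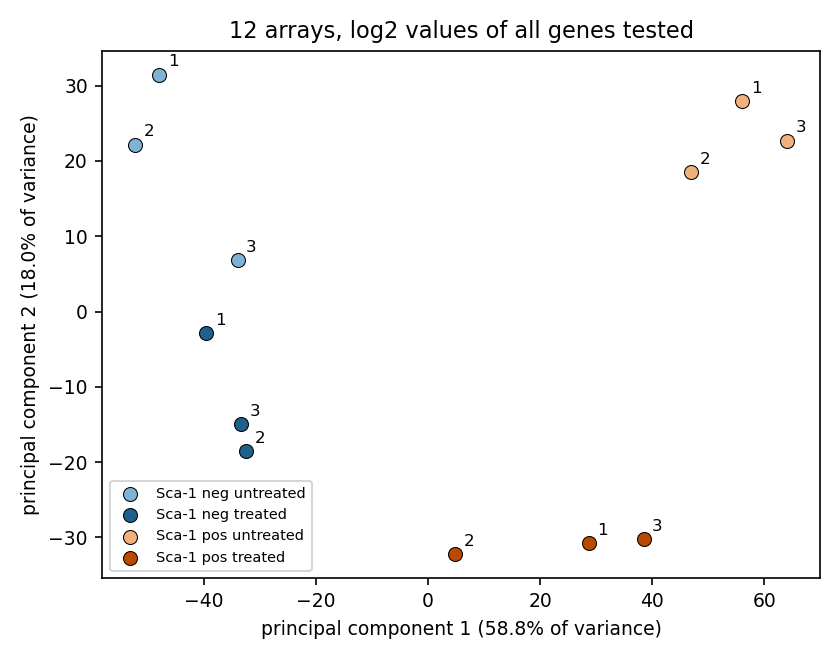
Principal components 1 (58.8% of variance) and 2 (18.0%) of the log2 expression values of 10203 genes, with each of the 12 arrays as a point marked by group and replicate number. Sca-1 pos and Sca-1 neg arrays lie on opposite sides of the first component, and Sca-1 neg untreated array 3 lies apart from arrays 1 and 2.

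The comparison of Sca-1 pos with Sca-1 neg cells of untreated mice asked how the fractions differed before injury. The largest rises in Sca-1 pos cells included genes of airway secretion and Chil3, which marks alveolar macrophages. Bpifb1, a secreted defence protein of the airway epithelium, was at least 196-fold higher in Sca-1 pos cells (n = 3 per group, limma adjusted p = 4.97e-07), with mean levels of 12.67 ± 1.04 (SD) and 4.78 ± 0.15, the latter below the level a probe needs to be detected. Bpifa1, of the same family, was 174-fold higher (log2 fold change 7.44 ± 0.61 SE), Tff2, a mucosal repair peptide, at least 117-fold and Scgb3a1, a secretoglobin of airway secretory cells, at least 88.5-fold. Chil4 and Chil3, chitinase-like proteins, were at least 146-fold and 165-fold (7.37 ± 0.45) higher, and Ear3, an eosinophil-associated ribonuclease, was at least 175-fold higher. The remaining large rises were Ltf, the iron-binding lactoferrin (77.1-fold), Chad (at least 57.8-fold) and Gabrp (67.1-fold).

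These 10 genes were detected on all 3 Sca-1 pos untreated arrays. By any probe of the gene, Bpifb1, Ear3, Bpifa1, Chil3 and Gabrp were detected on 2 Sca-1 neg untreated arrays, Chil4, Ltf and Chad on 1, and Tff2 and Scgb3a1 on 0. The probe used for Bpifb1 was detected on 0 of them. Chil3 with Chil4, Ear3, Bpifa1 and Bpifb1 belong to families of near-identical genes, so a probe may read more than its named gene. The largest falls were smaller. Stard4, a carrier of cholesterol, fell by 3.44 ± 0.55 on the log2 scale (10.8-fold, limma adjusted p = 0.000337), Pld1, a phospholipase, fell by 3.05 ± 0.28, Cygb, a globin, fell by 2.86 ± 0.36, and Il19, a cytokine, fell by 2.78 ± 0.58. Gpd2, a mitochondrial glycerol phosphate dehydrogenase, Wdr89, Snx30 and Crebbp, a transcriptional coactivator, fell by 3.32, 2.92, 2.69 and 2.72. The mitochondrial ND5 was at least 5.09-fold and Ttn at least 5.14-fold lower. Several of these stood unevenly among the Sca-1 neg untreated arrays: Crebbp was at 9.30, 8.24 and 6.15 on arrays 1 to 3. On the arrays of the other groups Crebbp stood between 4.78 and 6.63.

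Club cell and ciliated lists had the largest medians. Of 20 measured ciliated cell genes, 18 rose and 0 fell, also when adjusted over the list alone, with a median log2 fold change of 3.17 (camera adjusted p = 7.74e-13, adjusted p = 0.227 with an estimated correlation). Examples were Mlf1 (26.4-fold), Stmnd1 (18.9-fold), Cfap126, a protein of the ciliary axoneme (9.28-fold), and Ccdc39, needed to assemble motile cilia (at least 5.27-fold). Of 16 club cell genes, 14 rose and 0 fell, the same adjusted over the list alone, with a median of 4.09 (camera adjusted p = 1.03e-09, adjusted p = 0.208 with an estimated correlation). They included Chad, Scgb3a1, Gabrp and Aldh1a1, a retinaldehyde dehydrogenase (36.4-fold). Scgb1a1, the main club cell secretoglobin, was bright in both fractions (15.35 in Sca-1 pos and 14.45 in Sca-1 neg cells). The 6 measured basal cell genes had a median of 1.33, 0.82 with bounds: Itgb4, an integrin of basal attachment, rose by 2.80 and Sox2, a transcription factor of airway progenitors, was at least 1.38-fold higher, while Itga6 fell by 1.16. Adjusted over the list alone 4 rose and 1 fell, and the list did not pass (camera adjusted p = 0.108, adjusted p = 0.265 with an estimated correlation).

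Markers of leukocytes, endothelium and stroma were also higher in Sca-1 pos untreated cells. Of 13 macrophage genes, 11 rose and 0 fell (11 adjusted over the list alone), among them Chil3, Ctsk, a lysosomal protease (16.8-fold), Mrc1, the mannose receptor (at least 17.5-fold), and Clec7a, a receptor for fungal glucans (at least 7.64-fold). The macrophage median was 2.81, with camera adjusted p = 1.86e-07, and adjusted p = 0.227 with an estimated correlation. Of 23 endothelial genes, 19 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 1.86e-07, adjusted p = 0.227 with an estimated correlation). Their median was 1.12, or 0.65 with bounds, since most of those that rose were detected on no Sca-1 neg untreated array: Ramp2 was at least 4.51-fold, Tmem100 at least 2.99-fold, the tight junction gene Cldn5 at least 2.81-fold and Vwf, von Willebrand factor, at least 1.85-fold higher. The brightest endothelial members, Esam and Egfl7, fell by 1.02 and 0.67. A gene detected only on the Sca-1 pos untreated arrays passes the detection filter through that group alone, so it can only rise here. Of 16 fibroblast and smooth muscle genes, 8 rose and 1 fell, also adjusted over the list alone, with the matrix proteoglycan Dcn up by 3.71 and Gsn up by 2.98. The fibroblast and smooth muscle median was 0.94 (0.77 with bounds), with camera adjusted p = 0.00361, and adjusted p = 0.265 with an estimated correlation. All 4 mesothelial genes rose, also adjusted over the list alone, among them Msln at least 8.57-fold (median 2.31, 1.91 with bounds, camera adjusted p = 0.00764, adjusted p = 0.227 with an estimated correlation).

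Neutrophil and T and NK lists passed camera as well, and B cell and erythroid lists did not. Of 12 neutrophil genes 8 rose (8 and 1 fell adjusted over the list alone), with Ltf, Clec4d (at least 3.44-fold) and Mcemp1 (at least 3.67-fold) as examples. The neutrophil median was 1.22 (0.79 with bounds), with camera adjusted p = 0.00361, and adjusted p = 0.227 with an estimated correlation. Of 9 T and NK cell genes 6 rose, 6 also adjusted over the list alone, with Zap70, a kinase of T cell receptor signalling, at least 4.27-fold and Cd2 at least 2.70-fold higher. Cd3e, Cd3g and Lat were at least 1.27-fold, 1.31-fold and 1.37-fold higher. The brightest members, Cd8b1 and Prf1, stood at 10.62 and 9.23 in Sca-1 pos and at 10.25 and 9.50 in Sca-1 neg untreated cells. The T and NK cell median was 1.04 (0.78 with bounds), with camera adjusted p = 0.00413, and adjusted p = 0.227 with an estimated correlation. Of 6 B cell genes 3 rose and 2 fell (4 and 2 adjusted over the list alone; median 0.87, 0.30 with bounds), with Vpreb3 up by 2.19 and Ly6d down, at -1.29; camera gave an adjusted p of 0.366, and 0.437 was the adjusted p with an estimated correlation. None of the 4 erythroid genes passed by limma (median 1.52, camera adjusted p = 0.608, adjusted p = 0.846 with an estimated correlation).

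Type II and lipid genes went the other way. Of 27 type II genes 10 fell and 0 rose, 10 also adjusted over the list alone, among them Nkx2-1, the lung epithelial transcription factor (-0.70), Il33, an alarmin (-0.86), Lgi3 (-0.87) and S100g (-0.89). The type II median was -0.46, with camera adjusted p = 0.00979, and adjusted p = 0.437 with an estimated correlation. Of 28 genes of fatty acid and surfactant lipid synthesis 15 fell and 2 rose, the same adjusted over the list alone. The fatty acid and surfactant lipid synthesis median was -0.52, with camera adjusted p = 0.00761, and adjusted p = 0.265 with an estimated correlation. Agpat3, an acyltransferase, changed by -1.91, Acacb by -1.73 and Pnpla2, a triglyceride lipase, by -1.11, while the elongase Elovl6 was at least 1.18-fold higher. Of 18 genes of cholesterol synthesis 10 fell and 1 rose, 12 and 1 adjusted over the list alone: Stard4, Nsdhl (-1.77) and Lss (-1.28) fell and Ebp rose (1.47). The cholesterol synthesis median was -0.77, with camera adjusted p = 0.00361, and adjusted p = 0.344 with an estimated correlation. The 21 type I genes moved up, with 11 risen and 1 fallen, 13 and 1 adjusted over the list alone (median 1.03, camera adjusted p = 0.0102, adjusted p = 0.437 with an estimated correlation). Hopx rose by 2.67, Pdpn, a membrane protein of type I cells, by 2.58 and Sema3e at least 2.78-fold, and Col4a4 changed by -1.14.

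Of 20 genes of an injury-associated transitional epithelial state 13 rose and 1 fell, the same adjusted over the list alone, led by the tight junction gene Cldn4 (26.7-fold), Plaur, the urokinase receptor (3.36), and the keratins Krt19 (2.90) and Krt7 (1.69). The transitional state median was 1.11 (1.03 with bounds), with camera adjusted p = 0.00012, and adjusted p = 0.344 with an estimated correlation. Of 28 interferon response genes 18 rose and 1 fell, also adjusted over the list alone, with the antiviral Usp18 9.01-fold, Oasl2 6.39-fold and Rsad2 at least 4.12-fold higher. The interferon response median was 0.85 (0.78 with bounds), with camera adjusted p = 9.4e-06, and adjusted p = 0.227 with an estimated correlation. Of 25 acute phase and antimicrobial genes 12 rose and 1 fell, also adjusted over the list alone: besides Bpifa1, Cp, the copper carrier ceruloplasmin, was 56.0-fold, Pigr, which carries immunoglobulin A across epithelium, 15.4-fold and the bacterial lipoprotein receptor Tlr2 15.1-fold higher. The acute phase and antimicrobial median was 1.02, with camera adjusted p = 0.000113, and adjusted p = 0.227 with an estimated correlation. Of 28 chemokine and NF-kB response genes 14 rose and 3 fell, 14 and 4 adjusted over the list alone, with Ccl3 at least 12.7-fold, Tnf at least 9.42-fold and Il18 at least 6.63-fold higher. The chemokine and NF-kB response median was 0.81, with camera adjusted p = 0.0027, and adjusted p = 0.361 with an estimated correlation. Of 25 dissociation and immediate early genes 8 rose and 3 fell, also adjusted over the list alone, with Egr2 at 1.47 and Zfp36 at 1.19. The dissociation and immediate early median was 0.37, with camera adjusted p = 0.0432, and adjusted p = 0.491 with an estimated correlation.

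The other lists did not pass camera in untreated mice, with adjusted p between 0.0923 and 0.938, and between 0.227 and 0.94 with an estimated correlation. Of 22 genes of matrix and mesenchymal transition 9 rose and 4 fell, also adjusted over the list alone (median 0.47, adjusted p = 0.0923), with Vim, a mesenchymal filament, at least 12.6-fold higher. Of 25 Wnt genes 8 rose and 9 fell, 9 and 9 adjusted over the list alone (median -0.09, or 0.18 under median scaling, mean 0.09): the Wnt antagonist Wif1 rose 6.15-fold, Wnt4 at least 5.35-fold, and Notum, which inactivates Wnt proteins, changed by -2.53. Of 36 cell cycle genes 5 rose and 4 fell, also adjusted over the list alone (median 0.01, adjusted p = 0.622), with Uhrf1 at 1.74 and Cdt1 at -1.14. Of 10 MHC class II genes 2 rose and 1 fell, also adjusted over the list alone (median -0.15, mean 0.27). Of 17 MHC class I genes 2 rose, B2m by 1.22, and 1 fell, 2 and 0 adjusted over the list alone (median 0.35, adjusted p = 0.17), and of 23 ribosomal protein genes 2 rose and 1 fell, 1 and 0 adjusted over the list alone (median 0.07).

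In all, 4526 of 10203 genes changed in untreated mice, 2121 higher and 2405 lower in Sca-1 pos cells. Under median scaling 3958 changed, 3024 higher and 934 lower; that scaling moved the median of all genes from -0.06 to 0.26 here, from -0.02 to 0.20 for the fractions of treated mice, from 0.01 to -0.20 for treatment in Sca-1 neg and from 0.03 to -0.30 for treatment in Sca-1 pos cells. Without Sca-1 neg untreated arrays 1 and 2 the count was 1895, with array 3 alone in its group and assumed to vary like the other groups.

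The same comparison in treated mice is the one the series design puts forward: whether Sca-1 pos type II cells after injury express progenitor genes in general. Airway secretory and antimicrobial genes again led. Bpifb1 was 120-fold higher in Sca-1 pos than in Sca-1 neg treated cells (6.91 ± 0.43 SE, n = 3 per group, limma adjusted p = 5.6e-06), Tff2 99.7-fold (6.64 ± 0.55), Reg3g, an antibacterial lectin, at least 76.6-fold, Ltf 61.6-fold (5.95 ± 0.79) and Bpifa1 at least 36.0-fold. Scgb3a1 was at least 47.4-fold and Gp2, a receptor for bacteria, at least 16.1-fold higher. Cd177, a neutrophil surface protein, and Cp were 30.3-fold and 30.1-fold and Chad at least 25.2-fold higher. Cell cycle and interferon response genes were higher in Sca-1 pos treated cells as groups.

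Of 36 cell cycle genes 32 rose and 0 fell, 33 adjusted over the list alone, with a median of 1.58 (camera adjusted p = 1.52e-22, adjusted p = 0.11 with an estimated correlation). Cdk1, the kinase that drives entry into mitosis, was 9.56-fold higher (3.26 ± 0.34), Mcm6, a subunit of the replicative helicase, 5.03-fold, the mitotic kinase Aurkb at least 4.31-fold and the spindle motor Kif11 at least 1.55-fold. Of 28 interferon response genes 21 rose and 1 fell, 23 and 1 adjusted over the list alone: Ifit2 was at least 2.79-fold higher, Rsad2 rose by 2.14, Igtp by 2.05 and Cmpk2 by 1.56, and Irf1 fell by 0.57. The interferon response median was 1.32, with camera adjusted p = 1.34e-12, and adjusted p = 0.137 with an estimated correlation. Of 17 MHC class I genes 9 rose, 12 adjusted over the list alone, with the peptide transporter Tap1 at 1.52 and the proteasome subunit Psmb9 at 1.22. The MHC class I median was 0.93, with camera adjusted p = 5.55e-06, and adjusted p = 0.222 with an estimated correlation. Of 25 acute phase genes 12 rose, 15 adjusted over the list alone. The acute phase median was 1.12 (1.09 with bounds), with camera adjusted p = 1.82e-07, and adjusted p = 0.154 with an estimated correlation. Of 28 chemokine and NF-kB genes 7 rose, also adjusted over the list alone, with Tnfaip2 at least 4.9-fold higher and Tnf at 2.59. The chemokine and NF-kB median was 0.36 (0.34 with bounds), with camera adjusted p = 0.00307, and adjusted p = 0.378 with an estimated correlation.

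Airway, macrophage and fibroblast markers were also higher in the Sca-1 pos fraction of treated mice. Of 16 club cell genes 12 rose and 1 fell, 14 and 1 adjusted over the list alone, with Gabrp 28.8-fold and the cytochrome Cyp2f2 8.19-fold higher and Cbr2 at -0.69. The club cell median was 3.31, with camera adjusted p = 1.32e-11, and adjusted p = 0.11 with an estimated correlation. Of 20 ciliated cell genes 17 rose, 20 adjusted over the list alone, with Mlf1 7.2-fold and Fam183b 4.87-fold higher. The ciliated cell median was 1.74 (1.35 with bounds), with camera adjusted p = 2.67e-12, and adjusted p = 0.222 with an estimated correlation. Of 20 transitional state genes 10 rose, also adjusted over the list alone, led by Cldn4 (10.8-fold). The transitional state median was 0.73, with camera adjusted p = 7.1e-05, and adjusted p = 0.36 with an estimated correlation. Of 13 macrophage genes 6 rose, with 8 risen and 1 fallen adjusted over the list alone, with Chil3 14.1-fold higher. The macrophage median was 1.00 (0.60 with bounds), with camera adjusted p = 0.000843, and adjusted p = 0.251 with an estimated correlation. Of 16 fibroblast genes 5 rose, also adjusted over the list alone, with Mgp at 2.57 and Dcn at 2.51. The fibroblast median was 0.68 (0.65 with bounds), with camera adjusted p = 0.000384, and adjusted p = 0.225 with an estimated correlation. Among 12 neutrophil genes 3 rose, also adjusted over the list alone (median 0.22, camera adjusted p = 0.0337, adjusted p = 0.36 with an estimated correlation). Of 23 endothelial genes 1 passed, Plvap, at least 1.03-fold higher, also adjusted over the list alone. The endothelial median was -0.02, with camera adjusted p = 0.687, and adjusted p = 0.854 with an estimated correlation.

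Sterol and lipid genes were lower in Sca-1 pos cells of treated mice. Of 18 cholesterol synthesis genes 10 fell, with 12 fallen and 1 risen adjusted over the list alone. The cholesterol synthesis median was -1.05, with camera adjusted p = 5.55e-06, and adjusted p = 0.222 with an estimated correlation. Insig1, a sterol-regulated brake on cholesterol synthesis, fell by 2.14 ± 0.49 (limma adjusted p = 0.0091), and Nsdhl, Hsd17b7, Lss and Fdps stood at -1.67, -1.35, -1.26 and -1.07. Of 28 fatty acid and surfactant lipid genes 8 fell, 9 adjusted over the list alone, with Lpin1 at -1.31 and Acacb at -1.23. The fatty acid and surfactant lipid median was -0.39, with camera adjusted p = 0.00426, and adjusted p = 0.251 with an estimated correlation. The largest falls were ND5 (at least 5.29-fold), Bpifb5 (-2.28), Ppp1r1b (-2.24), Fgg, a chain of fibrinogen (-2.24), Apoe, a lipid carrier (-2.17 ± 0.47), Notum (-2.12 ± 0.28), the protease precursor Pgc (-2.09), Mapk8ip1 (-1.98) and Cygb (-1.91), besides Insig1. Type II genes did not pass as a list in treated mice, with 1 risen and 2 fallen of 27 (1 and 1 adjusted over the list alone; median -0.06, or 0.02 under median scaling, camera adjusted p = 0.377, adjusted p = 0.772 with an estimated correlation).

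Of 22 matrix genes 6 rose and 1 fell, also adjusted over the list alone, with Ccn1 at 1.76. The matrix median was 0.32, with camera adjusted p = 0.0201, and adjusted p = 0.153 with an estimated correlation. Of 25 dissociation genes 5 rose and 2 fell, 6 and 2 adjusted over the list alone, with Jund at 1.23 and Jun at -0.83. The dissociation median was 0.36, with camera adjusted p = 0.0234, and adjusted p = 0.467 with an estimated correlation. The remaining lists other than the progenitor list, those of type I, basal, mesothelial, T and NK, B, erythroid, Wnt, MHC class II and ribosomal protein genes, did not pass (camera adjusted p from 0.103 to 0.931); for type I genes the median was 0.06 and camera's direction was down. In all, 2169 genes changed, 1163 higher and 1006 lower; under median scaling 1754 changed, 1513 higher and 241 lower. The count was 1035 without Sca-1 neg treated array 1, 1394 without Sca-1 neg treated array 3, 1103 without Sca-1 pos treated array 1 and 1146 without Sca-1 pos treated array 3.

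As a list, stem and progenitor associated genes passed camera upward in Sca-1 pos cells in both states with the preset correlation, but members went both ways and the call in each state ended under several alternatives. In untreated mice 13 of 28 rose, 9 fell and 6 did not pass, the same adjusted over the list alone, with a median log2 fold change of 0.60, or 0.42 with bounds (camera adjusted p = 0.0457, adjusted p = 0.227 with an estimated correlation). Aldh1a1, whose enzyme activity is used to sort stem cells, rose 36.4-fold (5.19 ± 0.37 SE, n = 3 per group), and Prom1, which encodes the surface protein CD133, was at least 3.85-fold, Lmo2, a regulator of blood and endothelial development, at least 3.03-fold and the homeobox gene Meis1 at least 2.04-fold higher. Kit, the stem cell factor receptor, Hes1, Cd24a, Sox9, Sox2, Gata2, Myc, Id1 and Podxl also rose. Those that fell were Itga6, Axin2, Notch1, Ezh2, Id2, Runx1, Alcam, Nanog and Gata6, from -1.16 for Itga6 to -0.49 for Gata6.

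In treated mice 6 of the 28 rose, 1 fell and 21 did not pass, also adjusted over the list alone (median 0.39, 0.11 with bounds, camera adjusted p = 0.0201, adjusted p = 0.154 with an estimated correlation). Aldh1a1 was 12.1-fold higher (3.59 ± 0.37), Foxm1, a transcription factor of dividing cells, 2.27-fold, Prom1 at least 1.05-fold and Lmo2 at least 1.03-fold, Sox2 and Podxl also rose, and Notch1, a receptor in cell fate decisions, fell by 0.94. The interaction did not pass for the list (median -0.10, camera adjusted p = 0.348, adjusted p = 0.63 with an estimated correlation), with Foxm1 risen and Meis1, Prom1, Lmo2 and Kit fallen, 4 and 8 adjusted over the list alone. Of the 28 members 9 belonged to another list, such as Aldh1a1 to club cell and Foxm1 to cell cycle genes, and the club cell median stood at 4.09 in untreated and 3.31 in treated mice. With the other 19 members alone the list did not pass in untreated (median 0.69, adjusted p = 0.104) or treated mice (0.19, adjusted p = 0.205). Over all alternatives the adjusted p of the list ran from 0.000118 to 0.808 in untreated mice, where 16 members detected on all arrays had a median of -0.19, and from 0.0017 to 0.223 in treated mice. Same-numbered arrays of the fractions varied together in untreated mice (residual r from 0.131 to 0.281 across genes), and with the 6 arrays compared and the replicate number as a block the list did not pass there (median 0.60, adjusted p = 0.0514). For number 2 the r of 0.131 stood against 0.0908 for another number. Array 1 of Sca-1 neg untreated cells lacked Eif2s3y, which stood at 8.53 on array 1 of Sca-1 pos, so the numbers need not pair animals. In treated mice it did not pass under median scaling (median 0.50), without a filter (0.0599) or with genes detected on all 12 arrays (0.21). Leaving out Sca-1 neg untreated array 3 (median 0.62, adjusted p = 0.256) or Sca-1 pos treated array 2 (0.60, 0.0518) ended the call in untreated mice. The median in untreated mice was 0.40 without Sca-1 neg untreated array 1 or without Sca-1 pos untreated array 3, and in treated mice 0.25 without Sca-1 pos treated array 3.

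**Figure D2:**
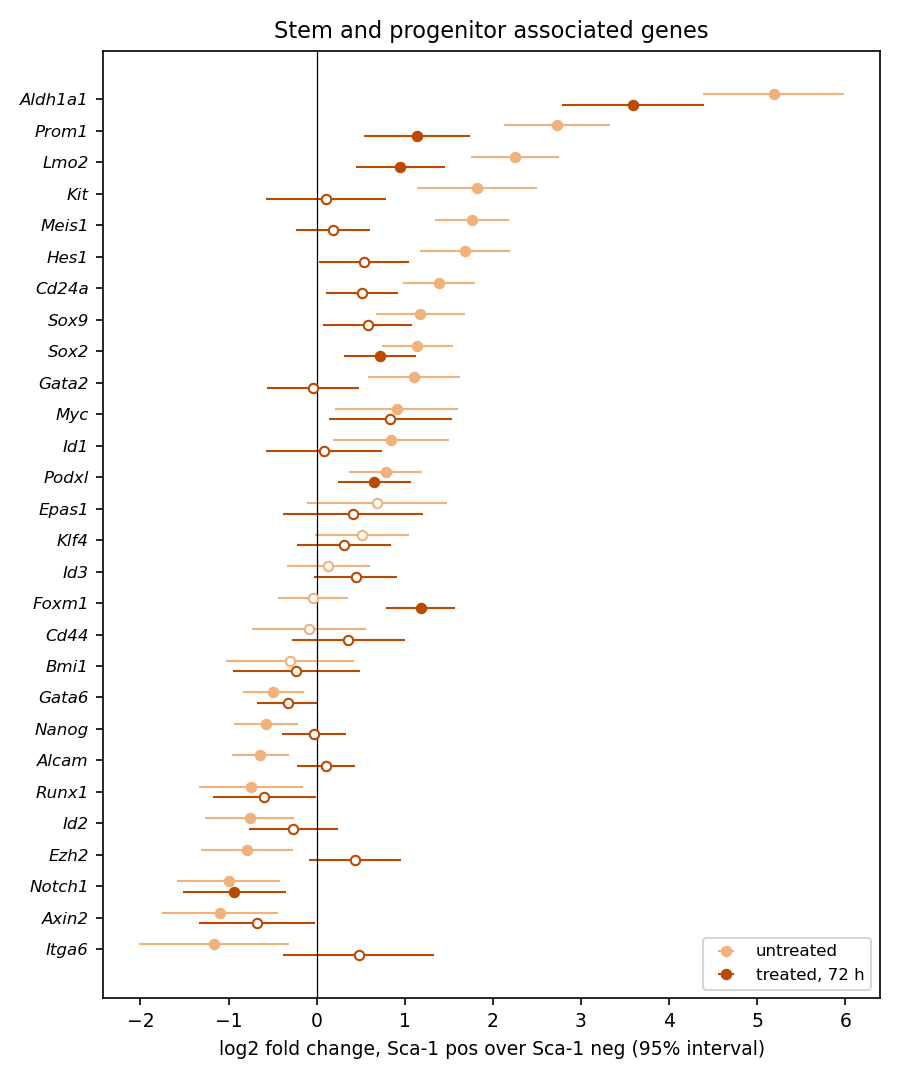
Log2 fold change of Sca-1 pos over Sca-1 neg cells for 28 stem and progenitor associated genes in untreated (light) and treated (dark) mice, with 95% confidence intervals and filled points where the limma adjusted p was under 0.05, n = 3 arrays per group. Aldh1a1 lies highest in both (5.19 and 3.59), and 13 genes rose and 9 fell in untreated against 6 and 1 in treated mice.

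The comparison of treated with untreated Sca-1 neg cells asked what the infection, together with the i.t. procedure, changed in type II cells that lack Sca-1. The largest single rise was in an acute phase gene. Saa3, a serum amyloid protein made in inflamed tissue, was at least 67.7-fold higher after infection (n = 3 per group, limma adjusted p = 0.00248), Orm1, an acute phase glycoprotein, 24.8-fold (log2 fold change 4.63 ± 0.74 SE) and the related Orm2 at least 9.98-fold. Pigr was 22.4-fold higher (4.49 ± 0.35, limma adjusted p = 9.09e-05) and Cfb, a factor of the alternative complement pathway, at least 7.67-fold. Il4i1, an amino acid oxidase of immune cells, was 12.6-fold, the immune receptors Tnfrsf9 at least 7.94-fold and Fcer2a 8.03-fold, the interferon-induced Ifitm3 7.85-fold and Ifi27l2a 3.13 on the log2 scale higher. Saa3, Orm1 and Orm2 belong to families of similar genes. Saa3 was uneven among Sca-1 neg treated arrays, at 8.78 on array 1 and at 11.75 and 12.86 on arrays 2 and 3. The mean log2 deviation of acute phase genes was also lower on array 1 (-0.79, against -0.07 and 0.25).

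Ccnd2, a cyclin of early cell cycle entry, fell 5.41-fold (-2.43 ± 0.42, limma adjusted p = 0.0137), Ccr6, a chemokine receptor, at least 4.38-fold, and Zdhhc21, Avpr1a, Tril, Espn and Cemip2 by 1.85, 1.73, 1.61, 1.59 and 1.59. Rn28s1, a ribosomal RNA sequence, Sox5 and Rc3h2 were at least 2.86-fold, 2.66-fold and 2.51-fold lower. Rn28s1 stood at 7.66 and 7.47 on Sca-1 neg untreated arrays 1 and 2 and at 5.25 on array 3. No measure of RNA quality was given, so a difference in RNA quality between these arrays was not tested and stays open for these falls and for the fractions of untreated mice.

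Of 28 interferon response genes 9 rose, 17 adjusted over the list alone, with Oasl2 5.89-fold, the ubiquitin-like Isg15 5.7-fold and the guanylate-binding Gbp3 at least 3.48-fold higher. The interferon response median was 0.93 (0.83 with bounds), with camera adjusted p = 2.19e-12, and adjusted p = 0.186 with an estimated correlation. Of 25 acute phase genes 8 rose, 13 adjusted over the list alone, with the iron-scavenging Lcn2 2.45-fold higher besides Pigr, Saa3 and Cfb. The acute phase median was 0.89 (0.65 with bounds), with camera adjusted p = 6.71e-12, and adjusted p = 0.186 with an estimated correlation. Of 17 MHC class I genes 4 rose, 11 adjusted over the list alone: B2m, the light chain of class I molecules, was 2.53-fold, and Nlrc5, a class I transactivator, at least 1.80-fold higher. The MHC class I median was 0.84, with camera adjusted p = 1.54e-10, and adjusted p = 0.186 with an estimated correlation. Of 36 cell cycle genes 3 rose, 5 adjusted over the list alone: Uhrf1 3.27-fold, Tk1 2.77-fold and Rrm2 at least 1.58-fold. The cell cycle median was 0.26, with camera adjusted p = 0.000125, and adjusted p = 0.957 with an estimated correlation. Of 28 chemokine and NF-kB genes 2 rose, 3 adjusted over the list alone, Cx3cl1 by 0.93 and Csf1 at least 1.70-fold. The chemokine and NF-kB median was 0.30, with camera adjusted p = 0.0079, and adjusted p = 0.963 with an estimated correlation. For MHC class II genes camera gave an adjusted p of 0.0261 (median 0.35, adjusted p = 0.996 with an estimated correlation), although 0 of 10 members passed by limma. None of the 28 progenitor genes passed (median -0.08, camera adjusted p = 0.539, adjusted p = 0.963 with an estimated correlation), and the other 20 lists did not pass.

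In all, 224 genes changed in Sca-1 neg cells, 126 higher and 98 lower; under median scaling 614 changed, 70 higher and 544 lower. The count rested on single arrays: it was 1649 without Sca-1 neg untreated array 3, 51 and 29 without Sca-1 neg untreated arrays 1 and 2, 147, 25 and 45 without Sca-1 neg treated arrays 1, 2 and 3, 139 without Sca-1 pos untreated array 2 and 118 without Sca-1 pos treated array 1. With the 6 arrays alone 1 gene passed. Without Sca-1 neg untreated arrays 1 and 2 together 0 genes passed by limma, with 879 at an unadjusted p under 0.05; array 3 is then alone in its group and assumed to vary like the other groups, so this 0 says little about single arrays.

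The comparison of treated with untreated Sca-1 pos cells asked the same of the fraction with Sca-1. Acute phase genes rose here as well: Saa3 213-fold (7.74 ± 0.79 SE, n = 3 per group, limma adjusted p = 0.000108), Orm1 60.4-fold (5.92 ± 0.74) and Orm2 43.2-fold (5.43 ± 0.67). Histone H2A genes rose with them, H2ac15 11.6-fold, H2ac12 11.0-fold, H2ac22 9.41-fold and H2ac7 8.03-fold, though near-identical sequences mean that their probes may read one another. Cell cycle genes rose almost throughout, and ciliated, endothelial and macrophage genes fell. Fcer2a, Bcl2l15 and Tnfrsf9 were 9.82-fold, 9.12-fold and 8.2-fold higher.

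The largest fall was that of Cyp2a5, a cytochrome P450 of xenobiotic oxidation (-3.57 ± 0.42, 11.9-fold, limma adjusted p = 0.00015), followed by Ear3 (-3.53 ± 0.54, 11.5-fold), the lysosomal leukocyte gene Laptm5 (9.28-fold), Prr33 (-3.18), the cytochrome Cyp4a12b (at least 6.78-fold), Mrc1 (8.82-fold), the carboxylesterase Ces1f (-3.05), Fxyd5 (-2.97), Slc15a3 (-2.94) and Ear10 (-2.90). Of 36 cell cycle genes 34 rose and 0 fell, also adjusted over the list alone, with the helicase subunit Mcm5 5.78-fold (2.53 ± 0.25), Aurkb 5.06-fold, the ribonucleotide reductase subunit Rrm2 at least 3.11-fold and Foxm1 3.36-fold higher. The cell cycle median was 1.94, with camera adjusted p = 7.4e-30, and adjusted p = 0.0542 with an estimated correlation. Over the same arrays 3 of 27 type II genes rose, 3 also adjusted over the list alone (median 0.28, camera adjusted p = 0.00637, adjusted p = 0.467 with an estimated correlation): Il33 by 1.11, Rab27a by 0.81 and Dlk1 at least 1.92-fold.

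Endothelial, ciliated, macrophage, club cell, type I, T and NK and mesothelial lists passed camera downward in treated Sca-1 pos cells, while B cell (median 0.42), neutrophil (0.08), fibroblast (-0.06) and erythroid lists did not pass. Of 23 endothelial genes 19 fell and 1 rose, also adjusted over the list alone: Ramp2, Tmem100, Cldn5 and Vwf were at least 4.39-fold, 3.02-fold, 2.84-fold and 1.86-fold lower, and Esam rose by 0.53. The endothelial median was -1.18 (-0.67 with bounds), with camera adjusted p = 2.57e-14, and adjusted p = 0.0542 with an estimated correlation. Members that passed the detection filter only through the Sca-1 pos untreated arrays could only fall here, so their falls repeat their rises in untreated mice. Of 20 ciliated genes 17 fell and 1 rose, 17 and 2 adjusted over the list alone: Stmnd1 fell 6.56-fold and Dnaic1, a dynein chain of cilia, by 2.23, while Mcidas, which switches on the program of multiciliated cells, rose by 1.58. The ciliated median was -1.91, with camera adjusted p = 4.88e-11, and adjusted p = 0.243 with an estimated correlation. Of 13 macrophage genes 9 fell, also adjusted over the list alone, with Mrc1, Ear10, Ctsk (-2.26) and the growth factor receptor Csf1r (-1.53). The macrophage median was -1.82, with camera adjusted p = 1.96e-07, and adjusted p = 0.161 with an estimated correlation. Of 16 club cell genes 5 fell, with 7 fallen and 1 risen adjusted over the list alone, with Bpifa1 at -2.37 and Gsta3 at -2.02. The club cell median was -0.84, with camera adjusted p = 0.00221, and adjusted p = 0.257 with an estimated correlation. Of 21 type I genes 7 fell, 11 adjusted over the list alone, with Cav1, the coat protein of caveolae, at -2.61. The type I median was -0.84, with camera adjusted p = 3.81e-05, and adjusted p = 0.294 with an estimated correlation. Of 9 T and NK genes 4 fell, 5 adjusted over the list alone (median -0.88, camera adjusted p = 0.00275, adjusted p = 0.168 with an estimated correlation), and of 4 mesothelial genes 2 fell, 3 adjusted over the list alone (median -1.20, -0.95 with bounds, camera adjusted p = 0.0135, adjusted p = 0.243 with an estimated correlation).

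Antigen presentation and interferon genes rose. Of 17 MHC class I genes 16 rose, also adjusted over the list alone, with H2-Q8 5.08-fold higher and H2-T10 and Psmb9 at 2.20 and 1.79. The MHC class I median was 1.39, with camera adjusted p = 3.47e-12, and adjusted p = 0.131 with an estimated correlation. Of 28 interferon genes 17 rose, with 22 risen and 1 fallen adjusted over the list alone, with Bst2, a tether of viral particles, at 2.18 and Irf7 at 1.98. The interferon median was 1.07, with camera adjusted p = 5.04e-11, and adjusted p = 0.153 with an estimated correlation. Of 25 acute phase genes 12 rose and 2 fell, also adjusted over the list alone, with the antiprotease Slpi at 2.18. The acute phase median was 0.82 (0.76 with bounds), with camera adjusted p = 4.93e-06, and adjusted p = 0.216 with an estimated correlation. Of 10 MHC class II genes 4 rose and 1 fell, 7 and 1 adjusted over the list alone, with Ciita, the master regulator of class II, at 0.97 and Ctss, a protease of antigen processing, at -2.02. The MHC class II median was 0.65, with camera adjusted p = 0.00729, and adjusted p = 0.467 with an estimated correlation.

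Of the 28 progenitor genes 3 rose and 8 fell after infection in Sca-1 pos cells, 3 and 9 adjusted over the list alone (median -0.21), and the list did not pass (camera adjusted p = 0.0625, adjusted p = 0.221 with an estimated correlation). Foxm1 (1.75), Ezh2, a histone methyltransferase (0.77), and Alcam (0.51) rose. Aldh1a1 (-1.69), Prom1 (-1.65), Lmo2 (-1.33) and Hes1 (-0.83) fell, and Kit, Meis1, Gata2 and Cd24a, each detected on no Sca-1 pos treated array, were at least 2.07-fold, 2.06-fold, 1.80-fold and 1.67-fold lower. The remaining 13 lists did not pass, with camera adjusted p from 0.16 to 0.799. Among them the median and the mean had opposite signs for chemokine and NF-kB (0.06 and -0.08), matrix (0.08 and -0.12), neutrophil (0.08 and -0.15) and basal cell genes (0.04 and -0.34), and under median scaling these medians were negative. In all, 1837 genes changed, 824 higher and 1013 lower; under median scaling 2240 changed, 304 higher and 1936 lower.

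**Figure D3:**
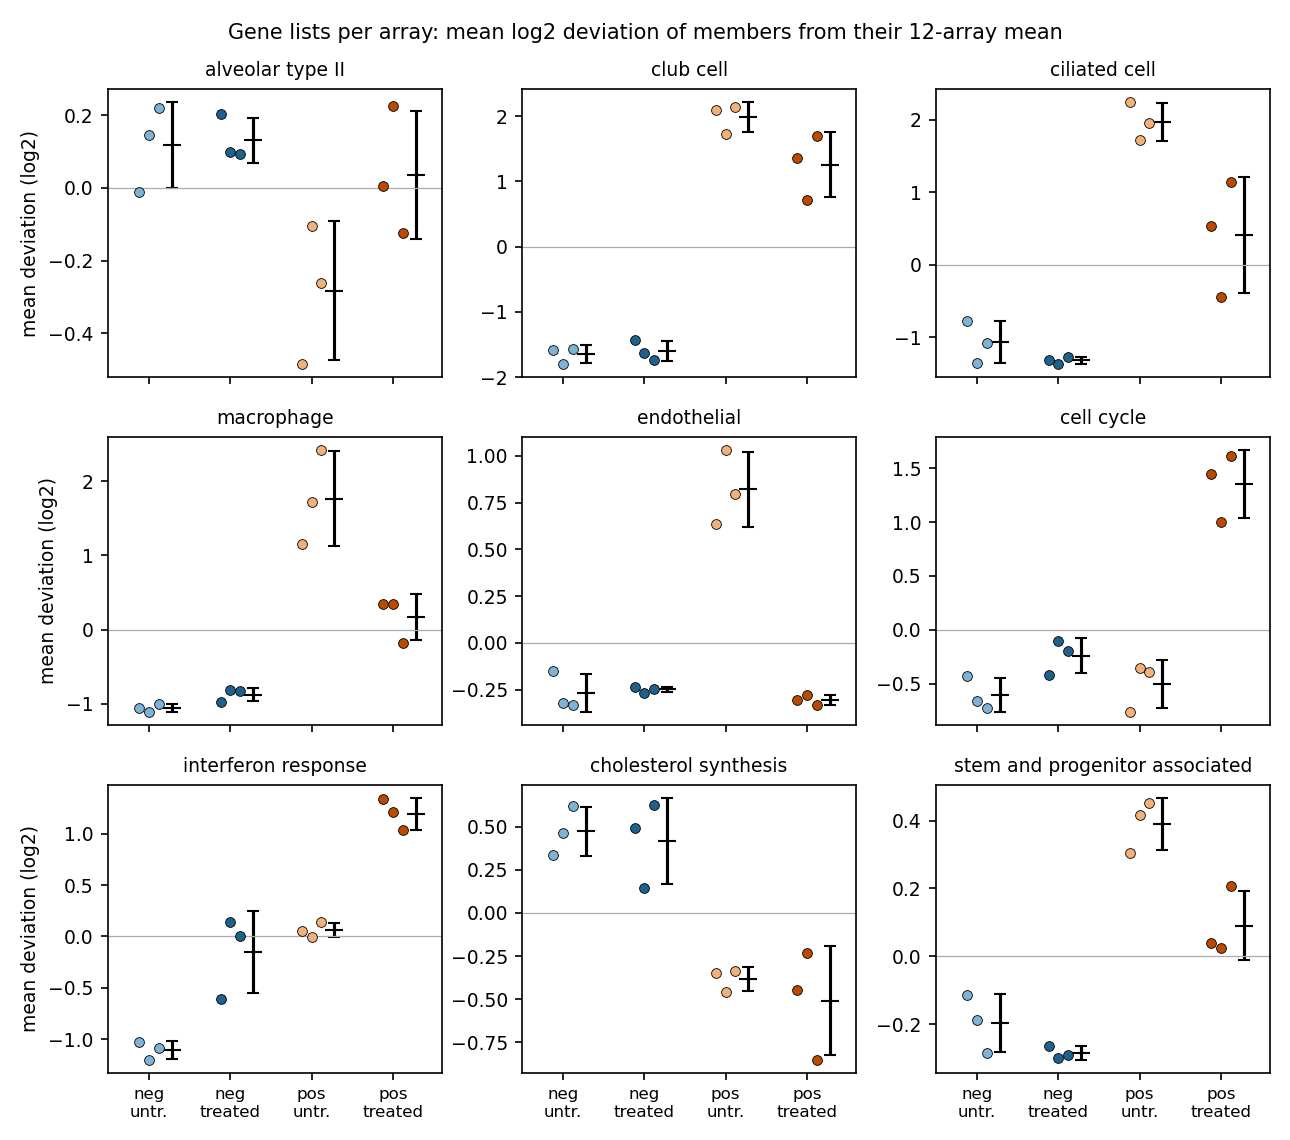
Mean log2 deviation of 9 gene lists on each of the 12 arrays, with dots for arrays and bars for the group mean ± SD (n = 3). Ciliated, macrophage and endothelial genes lie highest on Sca-1 pos untreated arrays, and cell cycle genes on Sca-1 pos treated arrays.

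The interaction asked whether infection changed Sca-1 pos cells differently from Sca-1 neg cells. Cell cycle genes rose more in Sca-1 pos cells: of 36, 21 had a positive interaction past the threshold and 0 a negative one, 32 adjusted over the list alone (median 1.41, camera adjusted p = 1.04e-23, adjusted p = 0.096 with an estimated correlation), among them Cdc20 (2.48), Prc1 (2.47), Plk1 (2.30) and Aurkb (2.17), all of mitosis. The 5 largest positive interactions were the histone genes H2ac22 (3.42 ± 0.59 SE, n = 3 per group, limma adjusted p = 0.0109), H2ac15 (3.34 ± 0.64), H2ac12 (3.29 ± 0.49), H2ac24 (2.99 ± 0.56) and H2ac7 (2.81 ± 0.50). The largest negative ones were Ear3 (-3.94 ± 0.76, limma adjusted p = 0.0151), Chil3 (-3.56 ± 0.64), Laptm5 (-3.43 ± 0.64), Chil4 (-3.37 ± 0.46) and Fcer1g, a signalling chain of immunoglobulin receptors (-3.23 ± 0.70).

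Endothelial genes had a negative interaction in 15 of 23, with 18 negative and 1 positive adjusted over the list alone (median -1.16, or -0.85 with values below the detection level set to it, camera adjusted p = 6.99e-15, adjusted p = 0.096 with an estimated correlation). Macrophage genes did in 6 of 13, 11 adjusted over the list alone (median -1.79, -1.67 at that level, camera adjusted p = 1.1e-08, adjusted p = 0.177 with an estimated correlation), and ciliated genes in 6 of 20, with 15 negative and 1 positive adjusted over the list alone (median -1.54, -1.65 at that level, camera adjusted p = 8.34e-09, adjusted p = 0.476 with an estimated correlation). Type I (median -0.97, 1 of 21 members), club cell (-0.91, or -0.87 at that level, 1 of 16), mesothelial (-1.37, or -1.10, 0 of 4 by limma) and T and NK genes (-0.88, or -0.66, 1 of 9), with 1, 4, 2 and 3 members adjusted over the list alone, also passed camera downward, with adjusted p from 0.000709 to 0.0149, and from 0.402 to 0.61 with an estimated correlation. Type II (0.19, 2 of 27 positive, also adjusted over the list alone) and MHC class I genes (0.51, or 0.56 at that level, 0 of 17 by limma) passed upward, with adjusted p = 0.0184 and 0.00562, and adjusted p = 0.676 and 0.63 with an estimated correlation. Interferon genes did not pass (median 0.29, camera adjusted p = 0.153, adjusted p = 0.72 with an estimated correlation). A group below the detection level was present for 19 of 23 endothelial, 8 of 13 macrophage and 9 of 20 ciliated genes. For a gene detected only on the Sca-1 pos untreated arrays, the filter fixed a negative interaction in advance. Such members are no separate support beside their rise in untreated mice and their fall after infection.

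In all, 467 genes had an interaction past the threshold, 133 positive and 334 negative; under median scaling 657 did, 97 positive and 560 negative. The count was 148 without Sca-1 neg untreated array 2, 1392 without Sca-1 neg untreated array 3, 163, 199 and 216 without Sca-1 neg treated arrays 1, 2 and 3, and 227 without Sca-1 pos treated array 1. Without Sca-1 neg untreated arrays 1 and 2 together 0 genes passed by limma, with 1530 at an unadjusted p under 0.05, again with array 3 alone in its group and the spread taken from the other groups.

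Genes such as Bpifb1, Tff2, Scgb3a1, Ltf and Chad were among the largest rises in Sca-1 pos cells in both states, and Saa3, Orm1 and Orm2 among the largest rises after infection in both fractions. Fold changes of Sca-1 pos over Sca-1 neg correlated at r = 0.78 (Spearman rho 0.74) across 10203 genes between untreated and treated mice, and those of treatment at r = 0.36 (rho 0.32) between fractions; genes are not independent replicates, and neither pair of comparisons shares arrays. In both states 1636 genes changed between fractions, 837 of them higher in both and 791 lower in both, where 242 and 237 would be shared if the calls were independent. After infection 98 genes changed in both fractions, 80 higher and 16 lower in both, where 10.2 and 9.73 would be shared.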

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

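All tests of the airway, macrophage and endothelial pattern and of the cell cycle pattern below were chosen after the results were seen; the tests of the spread among Sca-1 neg untreated arrays and the splits of the samples were chosen before, except for the count of residuals left on their own side of the interaction. In the next paragraph, genes had an interaction of fraction and treatment past the threshold by limma, and lists by camera with the preset correlation; with an estimated correlation no list passed. No outlier test was run on single arrays of these groups of 3. Array weights were lowest for Sca-1 neg untreated array 3 (0.251) and highest for array 2 (4.44), but their estimation did not fully converge.

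A negative interaction means that the change with infection was lower in Sca-1 pos than in Sca-1 neg cells. Negative values were those of Ear3 (-3.94), Chil3 (-3.56), Laptm5 (-3.43), Chil4 (-3.37), Fcer1g (-3.23), Mrc1 (-3.07), Slc15a3 (-2.97, limma adjusted p = 0.0109) and Ear10 (-2.90), of which Chil3, Mrc1 and Ear10 are in the macrophage list, and of Prr33 (-3.07), Cyp2a5 (-2.89), Fxyd5 (-2.77), Pigr (-2.58) and Ces1f (-2.38). Positive values were those of the histone genes H2ac22 (3.42), H2ac15 (3.34), H2ac12 (3.29), H2ac24 (2.99) and H2ac7 (2.81), and of Zdhhc21 (2.15), Pld1 (1.77) and Wdr89 (1.26, limma adjusted p = 0.0475). Among lists, the interaction medians were 1.41 for cell cycle, 0.51 for MHC class I and 0.19 for type II genes (adjusted p = 0.096, 0.63 and 0.676 with an estimated correlation). They were -1.79 for macrophage, -1.54 for ciliated, -1.37 for mesothelial, -1.16 for endothelial, -0.97 for type I, -0.91 for club cell and -0.88 for T and NK genes (adjusted p from 0.096 to 0.61 with an estimated correlation).

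Of 2460 detected probes without a single gene symbol, which no comparison of genes uses, 31 changed with treatment in Sca-1 neg and 294 in Sca-1 pos cells by limma.

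Markers of airway, macrophage and endothelial cells were higher in Sca-1 pos than in Sca-1 neg cells of untreated mice. For ciliated genes array scaling is excluded as the cause, since their list kept a median of at least 2.56 under 4 other scalings. The macrophage, club cell and endothelial lists were not put to this test. With genes detected on all 12 arrays the endothelial median was -0.67, over 3 genes. RNA of other cell types in the sorted fraction is a candidate explanation: within groups, members of each list varied together, with a mean residual correlation of 0.742 for ciliated, 0.320 for macrophage, 0.195 for club cell and 0.176 for endothelial genes, above the 95th percentiles of random lists (0.0676, 0.0881, 0.101 and 0.0562). The brightest club cell and ciliated markers, Scgb1a1 and Dynlrb2, stood at 15.35 and 12.84 in Sca-1 pos and at 14.45 and 10.43 in Sca-1 neg untreated cells. The brightest macrophage marker, Lyz2, which the type II list also holds, stood at 15.30 and 15.37, a level that would hide a small share of macrophages, and the next, Chil3, at 12.60 and 5.23. The brightest endothelial markers Esam and Egfl7 were lower in Sca-1 pos cells. How far the isolation of type II cells removed other cells was not tested. Expression of these genes by type II cells that carry Sca-1 would also make them vary together, and stays open as untested.

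Cell cycle genes were higher in Sca-1 pos cells after infection, with 34 of 36 risen. The cell cycle median exceeded the type II median by 1.66, and its lower quartile of 1.49 lay above the type II upper quartile of 0.50. This argues against a higher share of type II cells as the whole cause. It is not excluded, since the brightest type II genes could hardly rise. Lyz2 stood at 15.30 in Sca-1 pos untreated and 15.19 in Sca-1 pos treated cells, near the highest value of any probe, 15.39. Markers of macrophages and of T and NK cells (higher median of these lists -0.88) and of airway cells (higher median -0.84) fell. This argues against a net added share of cells with these markers. Of the 9 T and NK genes 7 had a group below the detection level. A list median also cannot show a gain of some cells beside a larger loss of others, so such a gain is not excluded. Division within any of the cell types present, B cells included (list median 0.42), stays open, and that type II cells with Sca-1 divide after infection may be a hypothesis that these arrays alone cannot settle.

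The 3 Sca-1 neg untreated arrays spread more than other groups, with Actb at 11.38, 12.39 and 13.84. The difference between arrays 1 and 3 did not resemble a sex difference, with a correlation of -0.14 across autosomal genes. That sex difference was taken between Xist and Eif2s3y arrays of treated Sca-1 neg cells, and genes are not independent replicates. Its Eif2s3y side was a single array, and untreated array 3 held both transcripts, so the sex of the animals is not excluded. Signal that single probes pick up could not be decided: the difference between arrays 1 and 3 correlated at 0.37 between 2 probes of a gene, against 0.74 for the fractions of untreated mice. Unspliced or genomic sequence could not be decided either, since probes without a symbol differed from the rest by 0.0756. RNA quality was not tested, since no measure of it was given, and stays open. Apart from the sex of the animals, no biological explanation was tested.

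Other splits of the arrays were fitted. For each comparison of 2 groups, 3 arrays against 3 make 10 splits, too few for a share under 0.05; 1 split, the real one, gave as many genes or as large a median. With the 6 arrays compared, the real count in untreated mice was 3678 and the highest other 0. It was 2626 against 1 in treated mice, 1 against 0 for treatment in Sca-1 neg and 1653 against 0 in Sca-1 pos cells. The median of the progenitor list was 0.60 against 0.29 for the highest other split in untreated and 0.39 against 0.16 in treated mice. Same-numbered arrays of the fractions varied together in untreated mice, and there the 3 other splits that part 3 pairs gave at most 0 genes by limma, as did the 6 that part 1 pair. Every other split mixes arrays of both groups, so a difference between the groups adds to its spread. Low counts and medians in these splits are therefore no evidence about chance. For the interaction, 3 of 100 reassignments of the residuals gave 467 genes or more, the real one included, a share under 0.05. That share is imprecise with 100 reassignments. Residuals were also exchanged between groups although the Sca-1 neg untreated arrays spread more, so chance is not firmly excluded. The highest other gave 1282, above the real count, which points to a structure of the samples: it left all 12 residuals on their own side of the interaction, so it held the real interaction with another spread within groups. The next gave 483 and left 10 there. For the interaction of the progenitor list 33 of 100 gave a median as far from 0, the highest other 0.29, so chance is not excluded.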

How the results depend on the processing

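Leaving out Sca-1 neg untreated arrays 1 and 2, leaving out progenitor genes of other lists, and the 6-array fit with the replicate block were chosen after the data were seen. Unless stated, the cause was not tested. Of the other results over all settings, named genes gave 2032 values with the same call, 176 weaker and 0 reversed, and lists 3369 the same, 61 stronger, 131 weaker and 5 reversed, a sign change of a list that passed in at least 1 of the 2 settings compared; a further 15 list medians that passed in neither changed sign under another scaling. Among the arrays left out in turn, the count of changed genes ran from 3358 to 5210 for the fractions of untreated mice, from 1035 to 2722 for those of treated mice, from 25 (without Sca-1 neg treated array 2) to 1649 (without Sca-1 neg untreated array 3) for treatment in Sca-1 neg cells, from 1310 to 2186 in Sca-1 pos cells, and from 148 to 1392 for the interaction. The progenitor median ran from 0.40 to 0.62 in untreated mice, from 0.25 to 0.45 in treated mice, and from -0.25 to -0.01 for the interaction.

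For treatment in Sca-1 neg cells the count was 134 without background correction, 135 from the deposited values, 145 without a filter, 614 under median scaling, 3460 with array weights and 1 with the 6 arrays compared, which leave fewer degrees of freedom. For the fractions of treated mice the 6 arrays compared gave 2626 in place of 2169, so fewer degrees of freedom need not lower a count. Requiring 2-fold, which can only lower a count, gave 2039, 880, 136 and 978 for the 4 comparisons of 2 groups. Array weights gave 3602 for the fractions of treated mice and 2125 for the interaction; their estimation did not fully converge. Every probe as a feature gave 7396 in untreated mice, since more features were tested. Without a filter the interaction count was 216. With genes detected on all 12 arrays, fewer genes, it was 123, and that of treatment in Sca-1 pos cells 1035. Without Sca-1 neg untreated arrays 1 and 2, where array 3 is alone and assumed to vary like the other groups, the counts were 1895 for the fractions of untreated mice, and 0 by limma for treatment in Sca-1 neg cells (879 at an unadjusted p under 0.05) and for the interaction (1530).

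The progenitor list lost its call in untreated mice without background correction (median 0.29, adjusted p = 0.0936), from the deposited values (0.29), under median scaling (0.83), with an offset of 50 (0.43), with an estimated correlation (0.60, adjusted p = 0.227), without genes of other lists (0.69), and with 6 arrays and the replicate block (0.60, adjusted p = 0.0514; 4003 genes). It lost it in treated mice under median scaling (0.50), without a filter (0.0599), with an estimated correlation (0.39, adjusted p = 0.154) and without genes of other lists (0.19), and with genes detected on all 12 arrays (0.21). Adjusted p ran from 0.000118 to 0.808 and from 0.0017 to 0.223 over all alternatives. That last filter removes genes dim in 1 group, such as Prom1 and Kit, and reversed the median in untreated mice (-0.19, 16 genes). It also reversed the endothelial (-0.67, 3 genes), neutrophil (-0.0045, 2 genes) and chemokine medians (-0.0654, 15 genes) there, and the endothelial medians of treatment in Sca-1 pos cells (0.43) and of the interaction (0.14). The replicate number as a block on all 12 arrays gave 4545, 2270, 292, 1852 and 625 genes and changed no call of the progenitor list. Slide as a block was not run, since slides were not given. Signal over background limits genes with a group below the detection level, whose folds between 2 groups are bounds.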

Other observations

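Families of genes that share a symbol stem, and Mcidas, were looked at after the values were seen; the test of the histone genes was chosen before its result was seen. Among 153 families with at least 8 measured members, Cfap genes, which build the axoneme of motile cilia, rose in 19 of 21 members in Sca-1 pos over Sca-1 neg cells of untreated mice and fell in 1 (median 3.21, camera adjusted p = 6.22e-10, adjusted p = 0.923 with an estimated correlation). After infection 17 of them fell and 0 rose in Sca-1 pos cells (median -1.95, camera adjusted p = 5.81e-12, adjusted p = 0.754 with an estimated correlation). Ift genes, which carry cargo along cilia, rose in 11 of 13 in untreated mice and fell in 1 (median 0.95, camera adjusted p = 0.018, adjusted p = 0.923 with an estimated correlation). After infection 6 Ift genes fell and 0 rose in Sca-1 pos cells (median -0.58, camera adjusted p = 0.00485, adjusted p = 0.754 with an estimated correlation). Cyp genes, cytochromes P450 that oxidise lipids and foreign compounds, fell in 11 of 23 and rose in 1 after infection in Sca-1 pos cells (median -0.86, camera adjusted p = 0.000267, adjusted p = 0.754 with an estimated correlation). Clec genes, lectin receptors mostly of myeloid cells, rose in 7 of 11 in Sca-1 pos cells of untreated mice (median 1.41, camera adjusted p = 0.0215, adjusted p = 0.923 with an estimated correlation). These directions held under the 4 other scalings, but the sizes did not: without background correction the medians in untreated mice were 1.96 for Cfap, 0.50 for Ift and 0.53 for Clec genes, and those of treatment in Sca-1 pos cells -1.31 for Cfap and -0.38 for Cyp genes.

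H2ac genes, which encode histone H2A and are mostly made as DNA is copied, rose in 10 of 13 members after infection in Sca-1 pos cells and fell in 2, H2ac18 and H2ac19 (-0.91), with a median of 1.27 (camera adjusted p = 0.000229, adjusted p = 0.754 with an estimated correlation). They rose in 9 of 13 and fell in 1 in Sca-1 pos over Sca-1 neg cells of treated mice (median 1.58, camera adjusted p = 5.23e-05, adjusted p = 0.911 with an estimated correlation). The interaction was positive in 8 and negative in 1 (median 1.37, camera adjusted p = 5.8e-06, adjusted p = 0.652 with an estimated correlation). In untreated mice the median was -0.00, and 0.39 under median scaling. Without background correction the 3 medians above were 0.98, 0.81 and 1.14. H2bc genes, which encode histone H2B and are also mostly made as DNA is copied, did not go with them. After infection in Sca-1 pos cells 0 of 10 rose and 1 fell by limma (median -0.39, camera adjusted p = 0.251, adjusted p = 0.967 with an estimated correlation). In Sca-1 pos over Sca-1 neg cells of treated mice 0 rose and 1 fell by limma (median -0.04, or 0.19 under median scaling), and the interaction median was -0.38. That the H2ac rises may belong to the same dividing cells as the cell cycle genes stays a hypothesis. The H2bc genes, looked at after the values were seen, did not rise with them, which leaves it undecided. The next test, chosen before its result was seen, came out as the hypothesis predicted, but a correlation over arrays cannot place both sets in the same cells. Within groups, the mean of the H2ac genes and the mean of the cell cycle genes correlated at r = 0.742 (rho 0.762) over 12 arrays, with exact permutation p = 0.0247 and 0.0231, two-sided, and r = 0.688 without the 2 arrays farthest from the median; 1 relation was computed. The probes of these near-identical genes may read one another, so the members are not independent.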
